A study of Mus musculus with 32 samples.

How the data were processed

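The data are RNA sequencing of LSK cells and granulocyte-macrophage progenitors (GMP) sorted from the bone marrow of C57BL/6 FLT3-ITD transgenic mice after treatment in vivo with vehicle, Lys05, AC220 or both (the combination), with 4 libraries in each of 8 groups and 32 in all. Per the labels' protocols, RNA was purified with a micro-scale column kit, amplified with a SMARTer v4 low-input kit, made into libraries with Nextera XT and sequenced in pairs on a NovaSeq. The values are raw counts per Ensembl gene that the authors deposited in 1 table. The submitters' processing notes list bcl2fastq 2.20, Trim Galore 0.6.5, STAR 2.7.3a, HTSeq 0.11.2, DESeq2 1.26.0 and the GRCm38 genome, without the role or order of each tool. The strand setting of the counting and the annotation release are not stated in the notes, so counts of genes that overlap on opposite strands or share sequence with paralogs may mix. The labels give each group 4 biological replicates and no batch, dose or time, and no numbers that link an LSK library to a GMP library.

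The deposited counts have 56246 gene rows and 5 summary lines (reads without a feature, ambiguous, not aligned uniquely and similar), which hold 15.2% to 30.9% of all counts of a library and stayed out of library sizes and tests. GENCODE M21 named 55230 of the rows, and the other 1016 held 0.00072% to 0.01% of gene counts. Gene counts ran from 35.7 to 55.9 M per library, so that a gene at 1 CPM has at least 35.7 counts before any scaling factor. Variation between replicates was above counting noise: between the libraries of a pair from the same group, the chi-square per gene ran from 35.4 to 1403. Genes are given as symbols of M21, for example Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489), Prtn3 (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), Ms4a3 (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851) and H2-Ob (ENSMUSG00000041538, chromosome 17, 34238903 to 34254414) on GRCm38.

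Counts were fitted in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors, estimateDisp and robust quasi-likelihood fits, once for the 16 LSK libraries (15730 genes), once for the 16 GMP libraries (14572 genes) and once for all 32 (17144 genes, for comparisons of the cell types). Group means in CPM come from the fit a comparison uses, so a gene's level differs between the fits. Vehicle Mpo was at 996 CPM in the LSK fit and 828 in the fit of all 32. In GMP it was at 9264 CPM in the GMP fit and 11273 in the fit of all 32. Within each cell type, Lys05, AC220 and the combination were compared with vehicle and the combination with each single drug, and the interaction of the drugs was tested. Across cell types, vehicle LSK was compared with vehicle GMP, and the difference between LSK and GMP was tested for each treatment's effect. All tests were two-sided, and p was adjusted over the genes of a comparison by Benjamini and Hochberg, with calls at an adjusted p under 0.05. Errors after ± are standard errors of the log2 fold change. Last zeros of log2 values in the results text are left off, and 1 such value is rounded to 1 decimal.

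The comparisons, 38 gene lists with 952 symbols, the rule for named genes and the first set of alternatives were written before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation and with fry. Counts of members higher or lower use the calls over all genes, or where stated an adjustment over the list alone. Library measures and list scores were compared by exact two-sided permutation tests over all splits, with 0.0286 the smallest p for 4 against 4. Effects were correlated across genes between comparisons that share no library. Every model-based count was set against 35 splits of the libraries (all splits of 4 against 4), 60 for interactions and 40 for differences between cell types, drawn with a fixed seed.

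Named genes follow a rule. It takes up to 6 rising and 6 falling genes with the largest change among those that passed, at a mean log2 CPM of at least 2 and with no overlap between groups, leaving out predicted, clone and pseudogene names and antigen receptor segments. It adds up to 4 members of a described list with the smallest p and 19 genes followed in every comparison (Flt3, Kit, Ppt1, Sqstm1, Map1lc3b, Hmgcs1, Myc, Pim1, Socs2, Cish, Dusp6, Ccnd1, Cdkn1a, Cdkn1c, Mki67, Trp53inp1, Mpo, Hlf and Mecom). Some items are not reported here. Where fewer than 12 genes passed, the 5 genes with the smallest p in each direction could be given as not passing. Other genes (Sel1l3) were chosen after their values were seen.

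The first set of alternatives was DESeq2 1.42.0, RLE factors, no filter on low counts, only the groups of a comparison, limma voom with quality weights and leaving out each library in turn. A covariate for Y-linked expression was not run, since all libraries had the same sex pattern. Of 2 alternatives chosen after seeing the data, one was an offset per library for a smooth trend of log2 CPM on transcript length and GC content (mgcv 1.9.3, 8 basis functions per term, length and GC from M21). The other was leaving out 5 GMP libraries whose median correlation with the other GMP libraries was under 0.8 (vehicle 1, AC220 1 and 3, and combination 3 and 4).

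The steps were tested on simulated data drawn from the real means, dispersions and library sizes. In them 200 genes at a mean log2 CPM above 2 were changed, and the primary granule list was raised 2-fold. The shares found below hold for genes at that level. For combination against AC220 in LSK (15277 genes), edgeR found 50 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 11 false among 158 calls, DESeq2 68 and 98 with 59 false among 232, and voom 47 and 91 with 9 false among 151. With a planted length trend edgeR gave 1662 false among 1815 calls, and 4 among 146 after the offset. That trend depended on length alone, a form the offset can remove, and the 200 genes were drawn without regard to length. It therefore does not show whether the offset separates a trend from a drug effect on short transcripts. For Lys05 against vehicle in GMP (14081 genes), edgeR found 0 of 100 and 8 of 100 with no false call, and DESeq2 4 and 34 with 77 false among 116. Camera called the planted list alone. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes falsely.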

Results

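RNA was measured in 32 libraries of sorted bone marrow cells from mice that carry a FLT3-ITD transgene, an activating internal tandem duplication of the receptor tyrosine kinase FLT3 found in acute myeloid leukemia. LSK cells are a gate of stem and early progenitor cells, and GMP are granulocyte-macrophage progenitors. Each population came from mice given vehicle, Lys05 (a lysosomal inhibitor that blocks autophagy), AC220 (quizartinib, a FLT3 kinase inhibitor) or both drugs, called the combination here, with 4 libraries in each of the 8 groups. The labels call these biological replicates and state no dose, time, batch or animal number. Gene counts ran from 35.7 to 55.9 M per library. All 32 libraries had the same sex pattern, with Xist at 0 to 0.302 CPM and the Y-linked list at 40.0 to 112 CPM in sum. The median correlation between the libraries of a group was 0.9, 0.927, 0.977 and 0.981 in LSK, and 0.869, 0.922, 0.785 and 0.734 in GMP with vehicle, Lys05, AC220 and the combination. The common biological coefficient of variation in edgeR was 0.475 in LSK and 1.06 in GMP.

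Vehicle LSK and vehicle GMP were compared to show how the populations differ before any drug. Myeloid granule and monocyte genes were lower in LSK. Mpo, the myeloperoxidase of primary granules, stood at 828 CPM in LSK and 11273 CPM in GMP (log2 fold change -3.77 ± 0.31, n = 4 each, edgeR quasi-likelihood test, adjusted p = 3.7e-09). The log2 differences of Elane, Prtn3 and Ms4a3 were -4.23, -3.47 and -3.63, and those of the monocyte genes Ly6c2, F13a1 and Csf1r -4.33, -4.8 and -3.07. Csf1r lost its call with the groups of the comparison alone (adjusted p = 0.0705). Of the primary granule list, 6 of 10 members were lower and 0 higher (9 lower adjusted over the list alone), and the list passed camera (adjusted p = 2.9e-25; adjusted p = 0.00116 with an estimated correlation). The monocyte list had 5 lower and 0 higher of 14 (adjusted p = 5.0e-12; adjusted p = 0.00116 with an estimated correlation). Stem cell genes and the lymphoid gene Dntt, which adds nucleotides at antigen receptor joints, were higher in LSK, with Dntt at 209 against 0.338 CPM. Gfi1b (25.9 against 0.0858 CPM), Epcam (15.7 against 0.0387 CPM), Il2ra (4.85 against 0 CPM) and the cytokine feedback gene Socs2 (3.32 ± 0.39, adjusted p = 2.2e-06) were also higher. Gpx3 (0.457 against 24 CPM), Chst13 (0.76 against 33.4 CPM) and Mefv (0.216 against 18 CPM) were lower. Of the stem cell and quiescence list, 7 of 27 members were higher and 0 lower, with a median log2 difference of 2.96 (adjusted p = 8.6e-12; adjusted p = 0.00116 with an estimated correlation). The interferon, STAT5 target and T and NK cell lists were higher and the unfolded protein response list lower, each also with an estimated correlation (adjusted p = 0.0492, 0.0111, 0.0291 and 0.0393), with median log2 differences of 1.36, 0.62, 2.99 and -0.68. Ifitm1 (2.96) and the endoplasmic reticulum chaperone Calr (-1.47) were members of those lists. Camera also called mitochondrially encoded (-3.09, mt-Nd6 at -3.8), histone (-1.41), ribosomal protein (-0.22, 13 of 79 lower, Rpsa at -1.42), secondary granule (-1.09), lysosome (-0.49, Hexa at -1.87 and Lamp1 at -1.54), immediate early (-1.01) and basophil and mast cell (-1.29, Hdc at -3.18) genes lower. It called MHC class II (1.63), stroma (2.35) and megakaryocyte (0.69) genes higher. None of these 10 lists passed with an estimated correlation (adjusted p from 0.163 to 0.492). The basophil call was lost without any of 27 of the 32 libraries and the megakaryocyte call without any of 24.

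In edgeR, 829 of 17144 genes differed between vehicle LSK and GMP, 303 higher and 526 lower in LSK. The count was 2071 in DESeq2 (964 higher and 1107 lower), 4329 with voom and quality weights (1998 and 2331) and 2646 without 5 weakly correlated GMP libraries (1243 and 1403), so the share that was higher moved from 36.6% to 46.5%, 46.2% and 47%. It fell to 513 (178 and 335) with no filter on low counts, to 502 without GMP vehicle library 3, 425 without LSK vehicle library 3 and 421 without LSK vehicle library 4, and rose to 1403 without GMP combination library 3. Several of the 19 genes followed in every comparison passed narrowly: Flt3 (110 against 28.5 CPM, 1.95 ± 0.54, adjusted p = 0.031), Ppt1, a lysosomal thioesterase (1.53 ± 0.42, adjusted p = 0.0291), and the stem cell factor Hlf (4.35 ± 1.23, adjusted p = 0.0356). Flt3 lost its call without GMP vehicle library 3 or LSK vehicle library 1, 2 or 4 (adjusted p up to 0.0831). Ppt1 lost it without GMP vehicle library 1, 3 or 4 or LSK vehicle library 2 or 3 (up to 0.13), and Hlf without any of the 8 vehicle libraries (up to 0.101). Cdkn1a, the cell cycle inhibitor p21, passed (1.95 ± 0.35, adjusted p = 9.4e-04). Kit was at 43.6 and 42.9 CPM (adjusted p = 0.992). Other calls that were lost without single libraries were H2-Ab1 (adjusted p = 0.0361, 6 libraries), Ly6a (0.0164, 3), Lck (0.0329, 7), S100a9 (0.0266, 5), Camp (0.027, 6), Isg15 (0.0491, 22), Mefv (0.0189, 2), Hyou1 (0.00895, 2), Pdia6 (0.0126, 1) and Hist1h1e (0.00837, 1).

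AC220 against vehicle in LSK asked what FLT3 inhibition does to stem and progenitor cells. The receptor genes Kit and Flt3 rose, Kit from 52.5 to 150.5 CPM (log2 fold change 1.52 ± 0.2) and Flt3 (chromosome 5 in GRCm38) from 132 to 443 CPM (1.74 ± 0.18, n = 4 each, edgeR, adjusted p = 6.3e-07). Myc (1.89 ± 0.22), the autophagy receptor Sqstm1 (2.21 ± 0.2) and the ERK phosphatase Dusp6 (2.28 ± 0.44) rose. Cdkn1a (-2.36 ± 0.21), the autophagosome gene Map1lc3b (-1.98 ± 0.13), the proliferation marker Mki67 (-1.46 ± 0.36) and the cell cycle inhibitor Cdkn1c (-1.54 ± 0.41) fell. Sub1 fell from 3040.4 to 123 CPM, Lsm7 from 2732 to 114, Tma7 from 2066 to 91.5, Ndufa12 from 2277 to 103 and Hist1h2bm from 90 to 3.32. Lpar5 rose from 0.0212 to 25.3 CPM, Atg9a from 0.0125 to 11.4, Rps6ka4 from 0.309 to 37.7 and Carm1 from 1.84 to 83.5. Glycolysis genes rose, with 21 of 26 members higher and 2 lower, among them Hk1 (2.76 ± 0.19), Pfkl (1.96 ± 0.14) and Pkm (1.78 ± 0.14; list adjusted p = 0.00122; adjusted p = 0.597 with an estimated correlation). Respiratory chain and ribosomal protein genes, with median transcript lengths of 1073 and 1059 bp, fell. They were 64 of 72 members of the nuclear-encoded oxidative phosphorylation list, such as Ndufb8 (-4.07 ± 0.14) and Uqcr10 (-3.12 ± 0.11), and 76 of 79 ribosomal protein genes, such as Rps16 (-2.48 ± 0.1), Rps14 (-2.4 ± 0.12) and Rpl5 (-2.07 ± 0.1). The oxidative phosphorylation list passed with adjusted p = 2.6e-67 (0.0172 as the adjusted p with an estimated correlation) and the ribosomal list with 4.2e-33 (adjusted p = 0.413 with an estimated correlation).

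These changes moved with a difference between the libraries. Counts on transcripts under 1000 bp made up 8.008% of gene counts in the 8 LSK libraries with AC220 and 18.66% in the 8 without it (two-sided exact permutation p = 0.000155, the smallest this design allows), and 19.51% and 20.5% in the 8 GMP libraries with AC220 and the 8 without (exact p = 0.335). In GMP it was 20.91% with AC220 (exact p = 1) and 18.12% with the combination (exact p = 0.0571), against 20.76% with vehicle. Genes with transcripts under 1000 bp had a median log2 fold change of -2.22 with AC220 in LSK, and those from 2000 to 4000 bp 0.70. With a length and GC offset for each library, chosen after seeing the data, these medians were -0.14 and 0.13. The 50 most abundant genes held 14.51% of gene counts with AC220 and 20.54% without.

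**Figure D1:**
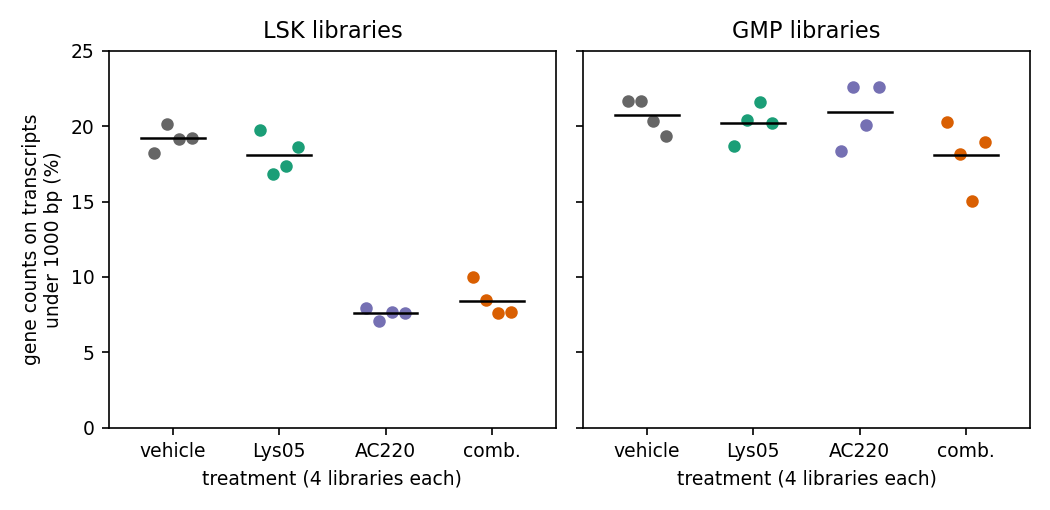
Share of gene counts on transcripts under 1000 bp (y axis, percent) in each LSK and GMP library by treatment (x axis), with points for libraries and lines for group means. The 4 AC220 and 4 combination LSK libraries lie below every other library, with means of 7.581% and 8.436% against 19.2% in vehicle LSK.

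In edgeR, 8632 of 15730 genes changed with AC220 in LSK, 4626 higher and 4006 lower, and with the offset 7039 did (3690 and 3349), of which 5126 were called in the same direction in both. With the offset Kit (0.78), Flt3 (0.75), Myc (1.23), Sqstm1 (1.27), Cdkn1a (-2.87) and Map1lc3b (-3.04) kept their calls. Mpo (0.98 ± 0.29) and the STAT5 target Cish (0.86 ± 0.25) rose without it and stood at -0.14 and -0.33 with it (adjusted p = 0.674 and 0.343), while Socs2 (-0.66) and the STAT5 target Pim1 (-1.52) were called lower only with it. Dusp6 lost its call with voom and quality weights (adjusted p = 0.227). Ppt1 (0.18), Hmgcs1 (0.35), Hlf (0.02), Mecom (-0.23), Ccnd1 (0.91) and Trp53inp1 (0.47) did not pass, and Trp53inp1 passed without vehicle library 1 (adjusted p = 0.0141). With the offset the oxidative phosphorylation list had 16 higher and 47 lower (median -0.79 against -2.58), and the ribosomal list 21 higher and 38 lower (median -0.21 against -1.6, adjusted p = 0.169). The glycolysis list stood at 0.45 with the offset (adjusted p = 0.0532). Mitochondrially encoded genes turned from 1 higher and 8 lower of 11 to 7 higher and 0 lower with the offset.

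**Figure D2:**
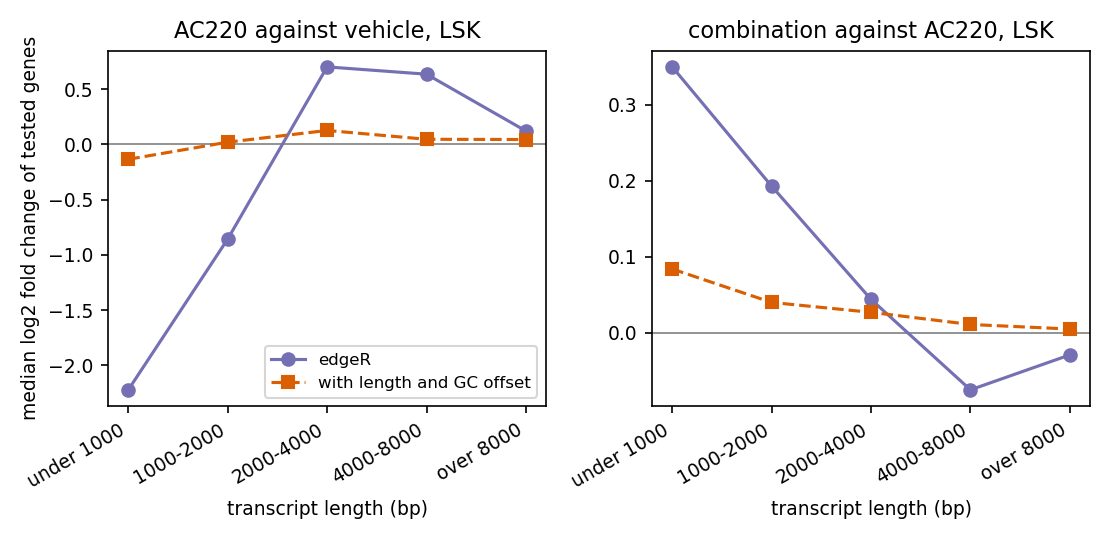
Median log2 fold change of tested genes (y axis) by transcript length class (x axis, bp) for AC220 against vehicle and combination against AC220 in LSK, in edgeR (solid) and with a length and GC offset (dashed). The class under 1000 bp lies at -2.22 in the first comparison and at 0.35 in the second, before the offset.

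The other fixed lists in AC220 against vehicle in LSK did not pass camera as sets, and their members went as follows. Among stress and recycling genes, 21 of 41 autophagy genes were higher and 11 lower, and 34 of 57 lysosome genes higher and 7 lower. Sterol genes had 14 higher and 3 lower of 25, the integrated stress response 18 and 6 of 37. The unfolded protein response had 10 and 5 of 21, heat shock genes 1 and 2 of 11, and NRF2 targets 9 and 5 of 20. For growth and survival, p53 targets had 10 higher and 3 lower of 28, G2/M genes 16 and 13 of 34. S phase genes had 20 and 16 of 43, MYC and ribosome biogenesis genes 20 and 13 of 45, BCL2 family genes 5 and 6 of 16, and replication-dependent histones 3 and 10 of 22. For signaling, STAT5 targets had 9 higher and 1 lower of 17, ERK feedback genes 7 and 0 of 14. FOXO targets had 8 and 4 of 17, interferon genes 14 and 7 of 42, NF-kB genes 10 and 1 of 23, and immediate early genes 3 and 2 of 13. Among cell type markers, stem cell genes had 3 higher and 7 lower of 27, primary granule genes 1 and 6 of 10, secondary granule genes 3 and 6 of 18. Monocyte genes had 4 and 3 of 14, dendritic cell and MHC class II genes 1 and 5 of 14, and tissue macrophage genes 3 and 0 of 14. Erythroid genes had 4 higher and 1 lower of 17, megakaryocyte genes 3 and 1 of 10, basophil and mast cell genes 0 and 3 of 7. B cell genes had 2 and 2 of 11, T and NK cell genes 1 and 2 of 12, lymphoid priming genes 6 and 0 of 8, and stroma and endothelium genes 1 and 1 of 7.

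The combination against vehicle in LSK showed antigen presentation genes falling beside the changes seen with AC220. H2-Ab1, a class II histocompatibility gene, fell from 22064 to 1106 CPM (log2 fold change -4.32 ± 0.77, n = 4 each, edgeR, adjusted p = 1.8e-04), and the dendritic cell genes Cd209a (-4.61 ± 0.73) and Batf3 (-4.46 ± 0.77) and the myeloid gene Aif1 (-4.52 ± 0.77) fell. Of the dendritic cell and MHC class II list, 10 of 14 members were lower and 0 higher, although the list did not pass camera (median -2.06, adjusted p = 0.119). Mpo rose from 996 to 3957 CPM (1.99 ± 0.29; 0.92 with the offset). Kit (1.25 ± 0.2), Flt3 (1.46 ± 0.18), Myc (2.05 ± 0.22), Sqstm1 (1.98 ± 0.2) and Dusp6 (1.96 ± 0.44) rose, and Cdkn1a (-2.32 ± 0.21), Map1lc3b (-1.95 ± 0.13), Mki67 (-1.44 ± 0.36), Cdkn1c (-1.29 ± 0.41) and Socs2 (-0.42 ± 0.14) fell. Carm1 rose from 1.84 to 68 CPM. Glycolysis genes had 18 higher and 2 lower of 26, such as Hk1 (2.66), Pkm (1.99) and Gapdh (1.51; list adjusted p = 1.2e-04; adjusted p = 0.425 with an estimated correlation). Oxidative phosphorylation genes had 6 higher and 60 lower of 72, such as Ndufb8 (-3.53; list adjusted p = 2.2e-56; adjusted p = 0.0324 with an estimated correlation). Ribosomal protein genes had 0 and 74 of 79, such as Rps14 (-2.09; list adjusted p = 1.2e-27; adjusted p = 0.425 with an estimated correlation). The short-transcript share was 8.436% in these libraries and 19.2% with vehicle (two-sided exact permutation p = 0.0286, the smallest for 4 against 4), and with the offset those medians moved from -2.07 to -0.51 and from -1.29 to -0.19. In edgeR 8153 of 15730 genes changed, 4448 higher and 3705 lower. Ppt1 did not pass (-1.01 ± 0.43, adjusted p = 0.0581), but it passed without vehicle library 1, Lys05 library 1 or combination library 4 (adjusted p down to 0.0251), with the offset (0.0405) and in DESeq2 (0.0282). Socs2 lost its call without combination library 1 or 4 (adjusted p up to 0.0719), Cdkn1c without vehicle library 3 (0.0677) and Dusp6 with voom (0.376).

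The combination against AC220 in LSK asked what Lys05 adds to FLT3 inhibition. Primary granule genes were higher with the combination: Ms4a3, expressed in granulocyte-monocyte progenitors, rose from 48.3 to 220.3 CPM (log2 fold change 2.19 ± 0.31, n = 4 each, edgeR, adjusted p = 0.0192). Prtn3, the granule protease proteinase 3 on chromosome 10, rose from 529 to 1224 CPM (1.21 ± 0.2, adjusted p = 0.0373). Ms4a3 averaged 223 CPM with vehicle and 312 CPM with Lys05. Mpo (1.01 ± 0.29, adjusted p = 0.146) and Ctsg (1.07 ± 0.24, adjusted p = 0.0646) did not pass, and both passed without combination library 1 (0.0239 for each). Of the list, 2 of 10 members were higher and 0 lower, 7 higher adjusted over the list alone, with a median log2 fold change of 0.64 (adjusted p = 9.4e-13; adjusted p = 0.078 with an estimated correlation). Respiratory chain genes were slightly higher: 15 of 72 passed (55 adjusted over the list alone), among them Ndufa4 (0.82 ± 0.12), Uqcrq (0.72 ± 0.13) and Atp5g3 (0.59 ± 0.11), with a list median of 0.49 (adjusted p = 3.6e-64; adjusted p = 0.0194 with an estimated correlation). Nme1 (0.67 ± 0.09), Etfb (0.75 ± 0.14), Mrps18c (0.81 ± 0.16), Ak6 (0.75 ± 0.14), the chaperonin Hspe1 (0.69 ± 0.13), Cks2 (0.51) and Rpl5 (0.47) also rose. The genes that fell were H2-Ob, a class II modulator in antigen loading (-1.33 ± 0.28, adjusted p = 0.0497), and the aldolase Aldoc (-1.02 ± 0.2). The dendritic cell and MHC class II list had no member past the threshold over all genes (11 of 14 lower adjusted over the list alone) and a median of -1.91 (adjusted p = 6.3e-16; adjusted p = 0.117 with an estimated correlation). Its members included Xcr1 at -2.65 ± 0.72, Cd209a at -2.27 ± 0.67 and Clec9a at -2.26 ± 0.73. Tissue macrophage genes stood at a median of 1.49 (adjusted p = 0.00127; adjusted p = 0.189 with an estimated correlation). C1qa stood at 5.11 against 0.667 CPM and C1qc at 5.88 against 1.06 CPM.

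**Figure D3:**
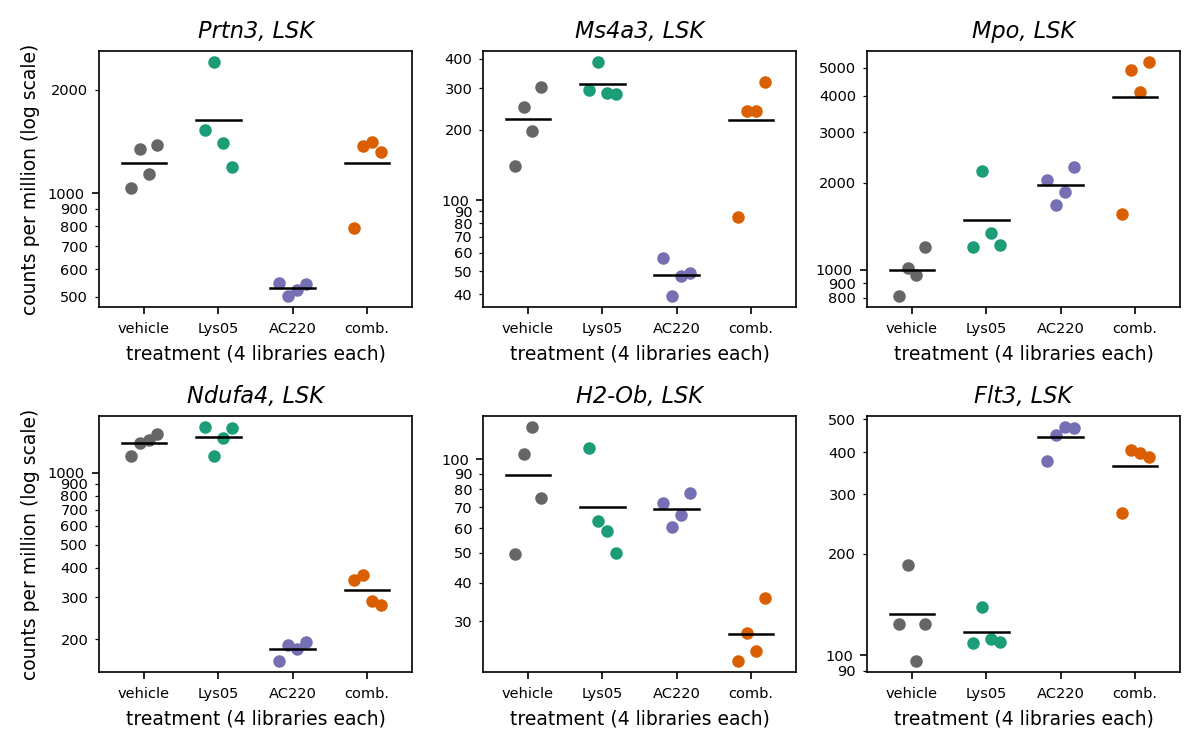
CPM (y axis, log scale) of 6 genes in each LSK library by treatment (x axis), with points for libraries and lines for group means. Ms4a3 averaged 48.3 CPM with AC220 and 220.3 with the combination, where combination library 1 lies below the other 3.

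Of these lists, the MYC and ribosome biogenesis (0.25, 10 of 45 members higher adjusted over the list alone), ribosomal protein (0.33, 31 of 79) and basophil and mast cell (0.66, Mcpt8 at 1.0) lists were also higher by camera in combination against AC220. The immediate early (-0.61, Btg2 at -0.81) and NF-kB (-0.34, Traf1 at -1.46) lists were lower. Their adjusted p with an estimated correlation was 0.117, 0.189, 0.117, 0.276 and 0.165. Smaller shifts passed camera for unfolded protein response (0.21, Manf at 0.48 and Calr at 0.46), G2/M (0.18), S phase (0.18), mitochondrially encoded (0.46) and histone (0.25) genes, which were higher. Sterol (-0.25, Srebf2 at -0.3), FOXO target (-0.16), BCL2 family (-0.16), T and NK cell (-0.6) and lymphoid priming (-0.65, Dntt at -1.05) genes were lower. None of these 10 lists passed with an estimated correlation (adjusted p from 0.189 to 0.521), and each lost its camera call without at least 1 library, most often combination library 1 (6 lists) or AC220 library 4 (4 lists).

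In edgeR 56 of 15730 genes changed between the combination and AC220 in LSK, 54 higher and 2 lower, and 1456 had an unadjusted p under 0.05. This count depended on the setting: it was 1 with the length and GC offset (Nme1, adjusted p = 0.035), 4 with RLE scaling, 5 with no filter, 2 with the groups of the comparison alone, 339 in DESeq2 and 2113 with voom. It was 0 without vehicle library 3 or 4, Lys05 library 1 or 3, AC220 library 2, 3 or 4, or combination library 2. It was 4 without vehicle library 1 or 2 or Lys05 library 2, 3 without AC220 library 1 or combination library 3, 11 without combination library 1 and 138 without combination library 4. Of the genes called higher, 25 of 54 had transcripts under 1000 bp, and the median length was 1026 bp against 3328 bp over all tested genes. With the offset the primary granule median was 0.58 and the oxidative phosphorylation median 0.2. Single calls were as fragile: Nme1 lost its call without any of 8 of the 16 libraries, Ndufa4 of 9, Ms4a3 of 10, Prtn3 of 12, Aldoc of 13, H2-Ob of 15 and the other 8 genes named as called of 14, with adjusted p up to 0.22. None of the 19 genes followed in every comparison passed: Flt3 was at -0.29, Kit at -0.26, Myc at 0.16 and Ppt1 at -1.19 (adjusted p = 0.303).

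**Figure D4:**
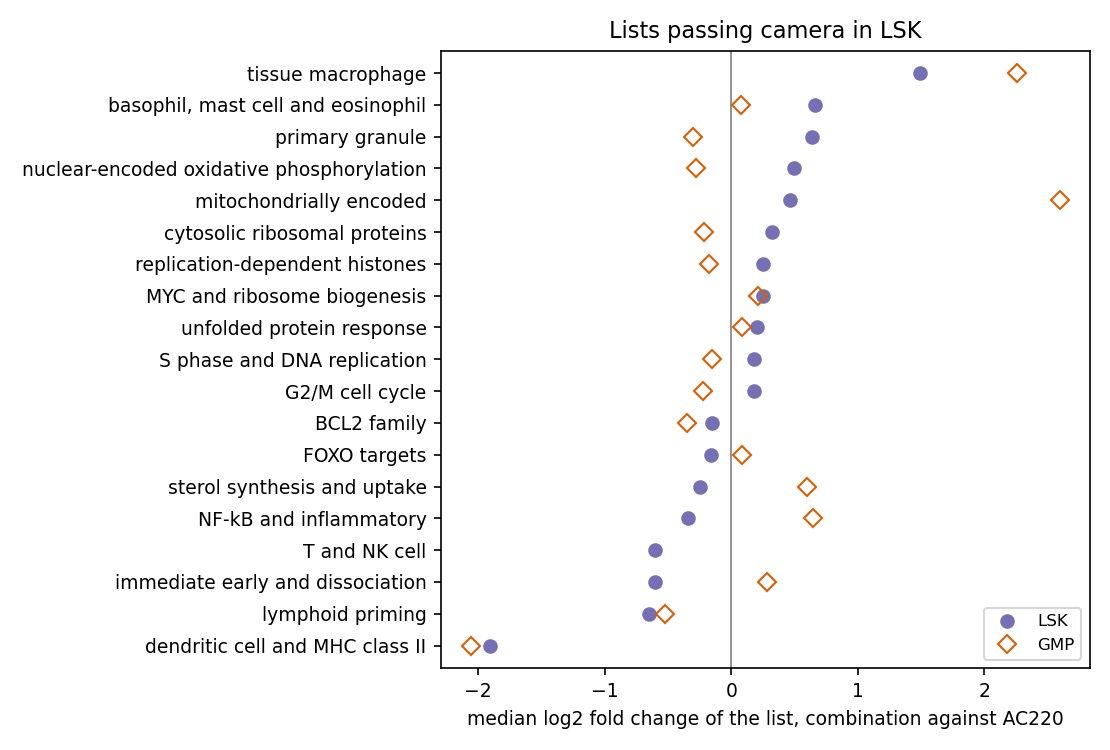
Median log2 fold change (x axis) of each fixed list that passed camera in LSK for combination against AC220 (y axis), with filled circles for LSK and open diamonds for the same list in GMP. The dendritic cell and MHC class II list lies at -1.91 in LSK and -2.06 in GMP, and the primary granule list at 0.64 and -0.3.

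The combination against Lys05 in LSK, which asks what AC220 adds to Lys05, gave changes of the kind seen with AC220 alone. Flt3 (1.63 ± 0.18, edgeR, n = 4 each, adjusted p = 1.5e-06), Kit (1.45 ± 0.2), Myc (1.62 ± 0.22), Sqstm1 (1.47 ± 0.2), Dusp6 (2.73 ± 0.46), Mpo (1.41 ± 0.29) and the sterol gene Hmgcs1 (1.12 ± 0.3) rose. Cdkn1a (-2.08 ± 0.21), Map1lc3b (-2.11 ± 0.13), Cdkn1c (-1.46 ± 0.41) and Socs2 (-0.46 ± 0.14) fell. Chpf2 rose from 0.346 to 19.9 CPM, Srsf4 from 0.84 to 34.8 and the cytoskeletal gene Vcl from 0.499 to 17.7, and Sub1 (-3.95) and Mylpf (-4.16) fell. Oxidative phosphorylation genes had 63 of 72 lower and 3 higher, such as Ndufb8 (-3.46; list adjusted p = 3.6e-58; adjusted p = 0.0289 with an estimated correlation). Glycolysis genes had 17 higher and 1 lower of 26, such as Hk1 (2.51; list adjusted p = 8.7e-04; adjusted p = 0.787 with an estimated correlation). Ribosomal protein genes had 71 of 79 lower (adjusted p = 5.8e-20; adjusted p = 0.787 with an estimated correlation), with a median that turned from -1.07 to 0.12 with the length and GC offset. In edgeR 7792 of 15730 genes changed, 4279 higher and 3513 lower. Mpo lost its call with the offset (adjusted p = 0.138), Dusp6 with voom (0.133) and Socs2 without combination library 4 (0.0506).

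Lys05 alone against vehicle in LSK gave no gene past the threshold in edgeR. Genes with an adjusted p of 0.0739, the smallest reached, did not pass: Cars2 (0.76 ± 0.13), Tnfrsf12a (1.85 ± 0.32), Tgds (1.18 ± 0.21) and the deacetylase Sirt6 (1.53 ± 0.28) were higher in value. Nlrc5, a regulator of class I antigen presentation (-0.91 ± 0.17), Emsy (-0.85 ± 0.16), Gpcpd1 (-1.34 ± 0.26) and Mcph1 (-1.03 ± 0.2) were lower in value. Each of these 8 passed without some of vehicle libraries 1, 3 and 4 and Lys05 libraries 1 and 4 (adjusted p from 0.00804 to 0.0497). Tmem158 (2.91 ± 0.51, 4.47 against 0.591 CPM) and Spata13 (-1.695 ± 0.32) also had an adjusted p of 0.0739 with all libraries. Autophagy and sterol genes did not pass, with Sqstm1 at 0.51 ± 0.19, Map1lc3b at 0.17 ± 0.12, Hmgcs1 at -0.78 ± 0.3 and Ppt1 at -0.19 ± 0.42. By camera, ribosomal protein (-0.2), mitochondrially encoded (-0.81, mt-Nd5 at -0.9), dendritic cell and MHC class II (-0.93, H2-Aa at -1.08) and immediate early (-0.39) genes were lower and primary granule genes (0.45, Mpo at 0.58) higher. Their adjusted p ran from 3.3e-07 to 0.0489 (adjusted p = 0.836 with an estimated correlation for each), and all but the ribosomal list lost the call without vehicle library 1, 2 or 3. In edgeR 0 of 15730 genes passed and 2718 had an unadjusted p under 0.05. DESeq2 called 830 (433 higher and 397 lower), voom 0 and the groups of the comparison alone 1. The count rose to 198 without vehicle library 3, 146 without vehicle library 4, 50 without Lys05 library 4, 41 without Lys05 library 1, 4 without vehicle library 1 and 1 without vehicle library 2.

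The interaction in LSK tests whether Lys05 acts differently with and without AC220. Genes of the respiratory chain and ribosome had positive values as lists. Ribosomal protein genes had a median of 0.53 (51 of 79 higher adjusted over the list alone, adjusted p = 1.3e-31; adjusted p = 0.492 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.45 (40 of 72, adjusted p = 2.5e-24; adjusted p = 0.492 with an estimated correlation). Mitochondrially encoded (1.3) and histone (0.56) genes were higher by camera (adjusted p = 1.6e-05 and 0.00189; adjusted p = 0.703 and 0.703 with an estimated correlation), the histone list not without combination library 1. MYC and ribosome biogenesis (0.21), primary granule (0.39) and heat shock (0.66) genes were higher and sterol (-0.14) and MHC class II (-0.99) genes lower by camera, each lost without any of at least 5 of the 16 libraries (adjusted p = 0.752, 0.752, 0.703, 0.752 and 0.907 with an estimated correlation). The smallest adjusted p was 0.153, of Sel1l3, a gene at a mean log2 CPM of -1.05. Genes at the next value, 0.222, included Btf3 (0.67 ± 0.13), Nme1 (0.68 ± 0.13), Uqcrq (0.88 ± 0.18), Ndufa4 (0.74 ± 0.17), Rpl38 (1.0 ± 0.24) and Ms4a3 (1.7 ± 0.43), with positive values, and Sirt6 (-1.68 ± 0.39) and Tgds (-1.24 ± 0.29), with negative values. Ppt1 was at -1.0 ± 0.6. In edgeR 0 genes passed and 1645 had an unadjusted p under 0.05. DESeq2 called 164 (86 higher and 78 lower) and voom 0. Leaving out LSK vehicle library 4 gave 4 genes, Lys05 library 4 gave 2, and vehicle library 1 or 2 gave 1.

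In GMP, Lys05 or AC220 alone against vehicle gave no gene past the threshold in edgeR. With Lys05, dendritic cell and MHC class II genes had a median of -1.26 (adjusted p = 3.3e-08; adjusted p = 0.101 with an estimated correlation), with Cd74 at -1.91 ± 0.6 and H2-Ab1 at -1.72 ± 0.55. Immediate early genes had a median of -1.0, with Dusp1 at -1.39 ± 0.53 (adjusted p = 4.9e-07; adjusted p = 0.0586 with an estimated correlation). Secondary granule genes of mature neutrophils stood at 0.47 (S100a8 at 0.87, Ngp at 0.77), primary granule genes at 0.27, tissue macrophage genes at 1.46, interferon genes at 0.27, glycolysis genes at 0.29 and NRF2 targets at 0.22. NF-kB (-0.6), histone (-0.8), mitochondrially encoded (-1.3, mt-Nd4 at -1.83), ribosomal protein (-0.16) and oxidative phosphorylation (-0.23) genes were lower. These 11 lists passed camera and none passed with an estimated correlation (adjusted p from 0.101 to 0.684), the mitochondrially encoded and histone lists alone kept the camera call without every single library, and the oxidative phosphorylation median turned positive without vehicle library 1 (0.11) and with voom (0.19). Single genes with Lys05, all with an adjusted p of 1, included Tmed3 (0.75 ± 0.26), the asparagine synthetase gene Asns (1.68 ± 0.65), Fcnb (1.34 ± 0.58), Supt5 (-2.07 ± 0.55) and Brd9 (-1.59 ± 0.43), and Ppt1 was at -0.11. With AC220, ribosomal protein genes had a median of 0.43 (16 of 79 higher adjusted over the list alone, Rps4x at 1.1 ± 0.24), MYC and ribosome biogenesis genes of 0.4, and mitochondrially encoded genes of -2.45 (mt-Cytb at -2.59 ± 0.97). These had adjusted p = 0.394, 0.327 and 0.415 with an estimated correlation. The share of mitochondrially encoded counts was 1.192% with AC220 and 5.774% with vehicle (two-sided exact permutation p = 0.0571), where vehicle library 1 had 12.67% and the others 2.33% to 5.186%. Camera also called S phase (0.28), oxidative phosphorylation (0.26), glycolysis (0.31) and heat shock (0.41) genes higher and NF-kB (-0.72), immediate early (-0.75) and histone (-0.89) genes lower (adjusted p from 0.327 to 0.449 with an estimated correlation). Of these, the oxidative phosphorylation and histone lists kept the camera call without every single library. The glycolysis median turned to -0.044 without vehicle library 1, -0.042 with voom and -0.103 without the weakly correlated libraries. The heat shock median turned to -0.102 without those libraries. Genes with an adjusted p of 0.299, the smallest reached, included the lysosomal mannosidase Man2b1 (1.57 ± 0.31) and Aimp1 (1.52 ± 0.35), with positive values, and Lypla2 (-3.98 ± 0.76) and Hist1h1d (-3.09 ± 0.65), with negative values. Kit was at 1.28 ± 0.54, Flt3 at 0.35 ± 0.74, Cdkn1a at 1.05 ± 0.45 and Mpo at 0.2 ± 0.26. Of 14572 genes, 159 had an unadjusted p under 0.05 with Lys05 and 1386 with AC220, and DESeq2 called 10 (5 higher and 5 lower) and 479 (52 and 427), and voom 732 (196 and 536) and 214 (81 and 133). Leaving out AC220 library 2 gave 1 gene for AC220.

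The combination in GMP was compared with vehicle, AC220 and Lys05. H2-Ob, on chromosome 17, fell from 31.1 CPM with AC220 to 0.238 CPM (log2 fold change -7.0 ± 1.02, n = 4 each, edgeR, adjusted p = 0.0422). Other antigen presentation genes did not pass against AC220, with Cd74, the class II invariant chain, at -3.25 ± 0.63 and H2-Ab1 at -2.85 ± 0.57, nor against vehicle, at -3.24 ± 0.63 and -2.6 ± 0.57. The dendritic cell and MHC class II list had medians of -1.85 against vehicle, -2.06 against AC220 and -0.8 against Lys05 (adjusted p = 2.3e-09, 6.3e-10 and 0.0121; adjusted p = 0.0821, 0.133 and 0.619 with an estimated correlation), the last lost without Lys05 library 1 or combination library 1. Tissue macrophage genes stood at 4.1, 2.26 and 2.68 (adjusted p = 0.162, 0.623 and 0.619 with an estimated correlation), with Vcam1 at 83.9 CPM against 4.87 in vehicle and 13.9 in AC220, and C1qb at 177 against 5.95 CPM in vehicle. Combination library 3 carried these means (Vcam1 at 254 CPM, lowest library 20; C1qb at 521, lowest 41.8), and without it the log2 fold changes against vehicle were 2.40 for Vcam1 and 3.34 for C1qb (4.10 and 4.90 with it; none passed). That library decided the macrophage calls against AC220 and Lys05, which were lost without it. Heat shock genes were higher against vehicle, with a median of 0.91 (adjusted p = 1.3e-05; adjusted p = 0.0417 with an estimated correlation), and against Lys05, with 1.15 (adjusted p = 1.2e-04; adjusted p = 0.0744 with an estimated correlation). They included Hsp90ab1 at 1.33 ± 0.31 and 1.78 ± 0.31 and Hsp90aa1 at 1.37 ± 0.41 and 1.66 ± 0.41. MYC and ribosome biogenesis genes stood at 0.58 against vehicle and 0.65 against Lys05 (adjusted p = 0.203 and 0.593 with an estimated correlation). By mean score of the libraries the differences were 0.22 and 0.07 (two-sided exact permutation p = 0.486 and 0.83), with combination libraries from 5.84 to 7.10. Members included Ncl at 1.21 ± 0.32 and 1.61 ± 0.32 and Odc1 at 1.7 ± 0.35 against vehicle. Against vehicle, Fubp1 (2.15 ± 0.4), Aimp1 (1.83 ± 0.35), Las1l (1.66 ± 0.33), Hspd1 (1.37 ± 0.28), the myeloid transcription factor Spi1 (-1.96 ± 0.36) and Tyrobp (-1.37 ± 0.28) had an adjusted p of 0.181, and H2-Ob (-6.32) the smallest, 0.103; Fubp1 and H2-Ob passed without AC220 library 1 (0.0431 for each), and H2-Ob also without combination library 2 (0.00942). Against AC220, Chd7 (2.46 ± 0.42), Hcls1 (1.98 ± 0.37), Siglece (-4.14 ± 0.81), Tbc1d7 (-2.8 ± 0.53) and Ppt1 (-1.31 ± 0.4) had adjusted p from 0.144 to 0.256. Against Lys05, Nars (1.91 ± 0.35), Tsc22d4 (1.95 ± 0.34), Spi1 (-2.18 ± 0.36) and Slpi (-1.76 ± 0.32) had an adjusted p of 0.0942, and Camp (-1.38) and Ngp (-1.44) a higher one. Hsp90ab1, Nars, Tsc22d4 and Spi1 passed against Lys05 without combination library 3 (0.0211, 0.0355, 0.0188 and 0.0355), and Spi1 also without Lys05 library 1 (0.0252). Mpo (-0.42 ± 0.26) and Flt3 (-1.14 ± 0.75) did not pass against vehicle.

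Further lists passed camera for the combination in GMP and none passed with an estimated correlation. Against vehicle these were ribosomal protein (0.29), glycolysis (0.53) and erythroid (1.88) genes, higher, and histone (-1.04) and immediate early (-0.56) genes, lower. Against AC220 these were mitochondrially encoded (2.6) and erythroid (1.69) genes, higher, and ribosomal protein (-0.22), oxidative phosphorylation (-0.28) and monocyte (-0.69) genes, lower, where the ribosomal and oxidative phosphorylation medians turned to 0.13 and 0.04 with the length and GC offset. Against Lys05 these were ribosomal protein (0.51), mitochondrially encoded (1.53) and erythroid (2.27) genes, higher, and secondary granule genes (-0.16), lower. Their adjusted p with an estimated correlation ran from 0.21 to 0.941, and only the histone list against vehicle, the mitochondrially encoded list against AC220 and the ribosomal list against Lys05 kept the camera call without every single library. In edgeR 0 of 14572 genes passed against vehicle (1601 at an unadjusted p under 0.05; 427 in DESeq2; 2 with voom; 1 without the weakly correlated libraries). Against AC220 1 passed (2035 at an unadjusted p under 0.05; 926, 0 and 49 by the others) and against Lys05 0 (1786 at an unadjusted p under 0.05; 508, 494 and 198). The H2-Ob call was lost without any of 12 of the 16 libraries (adjusted p from 0.0667 to 0.132). Leaving out combination library 2 gave 5, 7 and 4 genes in the order above, combination library 1 gave 2, 3 and 2, and combination library 3 gave 22 against Lys05. Leaving out AC220 library 1 gave 3 genes against vehicle, AC220 library 4 gave 3 against AC220 and Lys05 library 1 gave 1 against Lys05. With no filter, 6 genes passed against Lys05.

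The interaction in GMP gave no gene past the threshold. Utrn (3.68 ± 0.69), Chd7 (2.95 ± 0.58) and Trim44 (3.1 ± 0.69) had positive values and H2-Ob (-6.03 ± 1.21) and Siglece (-4.39 ± 1.05) negative values, each with an adjusted p of 0.422 in edgeR. Mitochondrially encoded genes had a median of 4.0 (mt-Nd4 at 4.15 ± 1.32; 11 of 12 higher adjusted over the list alone; adjusted p = 1.2e-12; adjusted p = 0.594 with an estimated correlation), beside a share of mitochondrially encoded counts that ran from 0.377% to 18.1% over the GMP libraries. Immediate early genes (1.35) were higher and secondary granule (-0.48) and MHC class II (-1.29) genes lower by camera, each lost without any of at least 3 of the 16 libraries (adjusted p = 0.594, 0.594 and 0.594 with an estimated correlation). In edgeR 0 genes passed and 1287 had an unadjusted p under 0.05. DESeq2 called 307 (216 higher and 91 lower), voom 1 and the fit without the weakly correlated libraries 5. Leaving out combination library 2 gave 1 gene.

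Whether each drug acts differently in LSK and GMP was tested on the difference itself. With AC220, Cdkn1a (-3.26 ± 0.5, adjusted p = 1.6e-05), Map1lc3b (-2.56 ± 0.4) and Mki67 (-1.96 ± 0.48) moved lower in LSK than in GMP, in edgeR with n = 4 per group. Lsm7 (-5.48, a transcript of 1129 bp), Bola1 (-5.2, 995 bp) and Mrps18c (-5.23, 820 bp) also moved lower in LSK. So did 57 of 72 oxidative phosphorylation genes such as Cox7c (-4.87) and Ndufa1 (-4.08; list adjusted p = 2.2e-73; adjusted p = 5.7e-04 with an estimated correlation) and 70 of 79 ribosomal protein genes such as Rps16 (-2.73; list adjusted p = 1.9e-61; adjusted p = 0.0156 with an estimated correlation). Of the glycolysis list 8 members were higher, such as Pkm (1.64 ± 0.28) and Gapdh (1.25 ± 0.33), of the NF-kB list 4, and of the primary granule list 3 were lower, such as Ms4a3 (-2.59 ± 0.44). These lists had adjusted p = 0.76, 0.332 and 0.854 with an estimated correlation. With the length and GC offset the log2 differences of Lsm7, Bola1 and Mrps18c were -4.49, -3.9 and -2.43, those of Cox7c, Ndufa1 and Rps16 -1.14, -1.7 and -1.15, and the medians of the oxidative phosphorylation and ribosomal lists moved from -2.59 to -1.0 and from -1.83 to -0.8. With it Ms4a3 (-0.83), Pkm (0.0) and Gapdh (-0.02, a reversed sign) did not pass. Flt3 (1.62 ± 0.74, adjusted p = 0.135) and Mpo (0.97 ± 0.4, adjusted p = 0.0936) did not pass, but Flt3 passed without GMP vehicle library 1 (0.0144) and Mpo without LSK combination library 1 (0.0384). The glycolysis list lost its call without any of 5 of the 32 libraries and the primary granule list without any of 7. In edgeR 2884 of 17144 genes differed, 1428 higher and 1456 lower in LSK, against 5564 with voom (3474 and 2090, 62.4% higher) and 5309 without the weakly correlated libraries (3126 and 2183, 58.9% higher), where the first share was 49.5%.

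With the combination, Mpo (2.54 ± 0.4, edgeR, n = 4 per group, adjusted p = 4.5e-05), Myc (2.93 ± 0.79) and Flt3 (2.8 ± 0.75) moved higher in LSK than in GMP, and Cdkn1a (-3.39 ± 0.5), Mki67 (-2.12 ± 0.48) and Map1lc3b (-1.86 ± 0.4) lower. Fanci stood at 15.3 CPM in LSK with the combination and 2.01 with vehicle, and at 0.128 and 5.42 CPM in GMP, and Trim14 at 37.6, 5.38, 0.604 and 19.1 CPM in that order. The Trim14 means in GMP rested on vehicle library 1 (59.4 CPM, lowest library 3.53) and combination library 1 (2.35, lowest 0), and the log2 difference of Trim14 was 6.03 without the first and 12.5 without the second. Of the oxidative phosphorylation list 53 of 72 members were lower and 1 higher (Ndufa1 at -3.17; adjusted p = 0.00511 with an estimated correlation). Of the ribosomal list 63 of 79 were lower (Rpl35a at -3.33; adjusted p = 0.0619 with an estimated correlation). Of the glycolysis list 8 of 26 were higher (Pkm at 1.68; adjusted p = 0.756 with an estimated correlation), a camera call lost without GMP vehicle library 2 or GMP combination library 1 or 2. With the offset those oxidative phosphorylation and ribosomal medians moved from -1.86 to -0.77 and from -1.39 to -0.88, and Mpo (1.14), Myc (1.8), Flt3 (1.5) and Pkm (0.19) did not pass. The glycolysis median turned to -0.082 with it (camera, adjusted p = 0.893). In edgeR 2182 of 17144 genes differed, 880 higher and 1302 lower in LSK (40.3% higher). The share was 56.7% with voom (1882 and 1436) and 59.3% without the weakly correlated libraries (3211 and 2201), and the calls were 476 higher and 1113 lower with the offset. DESeq2 called 3520, the groups of the comparison alone 1347. With Lys05, 0 genes differed in edgeR and 500 had an unadjusted p under 0.05. DESeq2 called 248 (152 higher and 96 lower) and voom 5. Mitochondrially encoded (0.54) genes were higher and secondary granule (-0.82) genes lower in LSK by camera, the first lost without GMP vehicle library 1 or GMP Lys05 library 3 or 4 and the second without GMP vehicle library 3 (adjusted p = 0.927 with an estimated correlation for both). The mitochondrially encoded median turned to -0.428 without GMP vehicle library 1 and rose to 2.469 without GMP Lys05 library 1. Brd9 (1.2), Actg1 (-0.85), Mpo (0.44) and Ppt1 (-0.14) had an adjusted p of 1.

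Effects were correlated across genes between comparisons that share no library, where genes are not independent replicates and the labels do not say whether LSK and GMP libraries share animals. The AC220 effects in LSK without and with Lys05 correlated (Pearson r = 0.713, Spearman rho = 0.799), as much as in 1 of 35 splits of the libraries, the real one, with the highest other |r| at 0.611. With the length and GC offset r was 0.639 and rho 0.733. Both effects set LSK libraries with the low short-transcript share against those without it, so a shared library difference cannot be told apart from the drug here. The Lys05 effects in LSK without and with AC220 gave r = 0.0745, with 7 of 35 splits as large, and rho = 0.133, with 1 of 35, the real one (highest other 0.116), and the sign of r turned without LSK AC220 library 1 (-0.002). In GMP the AC220 effects without and with Lys05 gave r = 0.124 and rho = 0.0922 (10 and 12 of 35), with r from 0.040 without GMP AC220 library 1 to 0.201 without GMP AC220 library 4. The Lys05 effects without and with AC220 in GMP gave r = -0.0305 and rho = -0.0261 (16 and 25 of 35; r = 0.012 without GMP vehicle library 3). The Lys05 effects in LSK and GMP gave r = 0.136 and rho = 0.222, just above the other splits (highest 0.133 and 0.215), and r depended on single libraries, from 0.090 without GMP Lys05 library 3 to 0.212 without GMP Lys05 library 1. The AC220 effects in LSK and GMP gave r = -0.0236 and rho = -0.00469 (4 and 30 of 35). Over genes at a mean log2 CPM of at least 4, r was 0.28 and 0.957 for the Lys05 and AC220 effects in LSK, -0.0678 and 0.235 for those in GMP, 0.414 for the Lys05 effects in LSK and GMP and 0.0168, a turned sign, for the AC220 effects in LSK and GMP. These 6 correlations were 1 family and had no p other than the split counts.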

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

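The tests of sequencing depth, of a preparation batch and of GMP-like cells below were chosen after the results were seen, as were the length and GC offset and the fits without 5 weakly correlated GMP libraries that others rest on.

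Single libraries stood far from the other 3 of their group (the gap to the nearest library over the whole range, by Dixon's criterion) in 30 of 216 groups of values tested. For normal values chance flags about 1 in 20 groups, or 10.8. Many of the values were CPM of single genes without a log, which can be skewed, so chance may flag more. In GMP combination library 3, Mpo was lower (4447 CPM) and Dusp6 (56.43), Ccnd1 (4.75), Cdkn1c (1.376) and Hlf (8.307) higher. In GMP Lys05 library 1, Trp53inp1 (5.16 CPM), Hlf (7.551), Mecom (5.184), the reads not aligned uniquely (16.23%) and the mitochondrially encoded share (9.194%) stood apart. GMP vehicle library 1 had 9022 genes at 1 CPM or more, 7.072% ambiguous reads and Flt3 at 2.183 CPM, and GMP vehicle library 2 Ccnd1 at 4.356 CPM. In GMP with AC220, Kit stood at 168.2 CPM in library 1, Sqstm1 at 67.63 in library 3 and Cish at 2.734 in library 4, and Cish stood at 3.163 CPM in GMP combination library 4. LSK vehicle library 1 was apart for the sterol gene Hmgcs1 (28.1 CPM) and for Hlf (23.93). LSK combination library 1 was apart for Flt3 (263.9 CPM), Mecom (17.16) and reads without a feature (10.09%), and library 4 for Ccnd1 (5.763 CPM). In LSK with Lys05, Flt3 stood at 139.2 CPM and Mpo at 2202 in library 2, Dusp6 at 1.041 in library 4 and the share of the 50 most abundant genes at 22.92% in library 1. In LSK with AC220, Mki67 stood at 189.4 CPM in library 1 and Mecom at 21.16 in library 2.

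The effect of AC220 differed between LSK and GMP in 2884 genes by a test of the difference itself, among them Map1lc3b (-2.56), Cdkn1a (-3.26) and Mki67 (-1.96). That of the combination differed in 2182 genes, among them Flt3 (2.80), Map1lc3b (-1.86), Myc (2.93), Cdkn1a (-3.39), Mki67 (-2.12) and Mpo (2.54). As many genes came from 1 of 40 splits of the libraries, the real one, for both (highest other 9 and 4). These splits exchanged treated and vehicle libraries within each cell type, so they test for no effect in either population. They cannot decide whether the effects in LSK and GMP differ by chance. For Lys05, with 0 genes, all 40 splits gave as many (highest other 0). The splits do not test a preparation batch that holds the LSK libraries with AC220, which would enter both differences. With the length and GC offset 2093 and 1589 genes differed. Of these, 1489 and 1153 were called in the same direction without it. Flt3, Myc and Mpo did not pass with the offset for the combination.

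With AC220 against vehicle in LSK, 8632 genes changed, and the LSK libraries with AC220 held fewer counts on short transcripts. A smooth trend with transcript length and GC, of the form the offset removes, is argued against as the whole cause. The number of calls after the offset was 81.5% of that before. That share includes calls that were new or turned, and 5126 of the 8632 genes were called in the same direction after it. A depth difference is argued against by a ratio of mean gene counts of 1.12. A preparation batch that holds the LSK libraries with AC220 would be confounded with the drug and cannot be told apart from it, since the labels give no batch. The short-transcript share, for which 0 of the 16 LSK libraries lie on the other side, raised this explanation and so does not test it. A biological effect of FLT3 inhibition on these genes stays open as well. Splits of the libraries gave as many genes in 1 of 35 for AC220, the combination against vehicle and the combination against Lys05. The real values were 8632, 8153 and 7792 and the highest others 1, 0 and 0. The real split alone is the fewest this design can give (two-sided permutation p = 0.0286, not adjusted over comparisons). It makes chance unlikely for these groupings without excluding it.

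With the combination against AC220 in LSK, the primary granule and respiratory chain lists passed camera, with 2 of 10 and 15 of 72 members called over all genes. With an estimated correlation the granule list did not pass (adjusted p = 0.078) and the respiratory chain list did (0.0194), and by library score the granule difference of 0.75 did not pass either (adjusted p = 0.19), so that its rise is not settled. After the offset the primary granule median was 91.4% of its value before, which argues against the length trend for that list, and the oxidative phosphorylation median 41.7%, between the bounds set for a cause and for none, so that a length trend stays open for it. A share of GMP-like cells that passed the LSK sort, which the Sca-1 gate would remove, may bring granule transcripts. The 6 abundant primary granule genes needed different shares, by their rise over their vehicle GMP level, from 1.2% (Elane, standard error 0.52) through 5.25% (Prtn3, 1.1) to 15.1% (Mpo, 6.4), with a heterogeneity p of 4.6e-05 and at most 0.00762 over the 4 GMP groups as references. Elane, the most abundant of them in GMP, would need 1075 to 1654 CPM at the median share of the others, and the highest combination library had 800.2 CPM. These shares use CPM without the offset. Short transcripts held 8.008% of gene counts in LSK libraries with AC220 and 20.76% in vehicle GMP libraries. Such a difference can change the shares gene by gene, so unequal shares cannot decide whether GMP-like cells are the whole cause. A wider set of 23 genes was tried first and its extremes decided nothing, because the highest share (Lars2, 62.8%) had an error of 78. GMP-like cells as part or whole of the cause, cells of another profile and an effect of Lys05 on LSK cells stay open. Of the splits, 1 of 35 gave as many genes as the real 56 (highest other 0).

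In GMP few or no genes were called for any treatment. A few weakly correlated libraries are a candidate cause: without 5 of them up to 198 genes were called (the combination against Lys05, 0 with all libraries), while Lys05 and AC220 alone had no such rise. The 198 calls set combination libraries 1 and 2 against 4 Lys05 libraries. Since the 5 libraries were picked for low correlation, some rise may follow from the pick itself, so the cause is not settled. On simulated data for Lys05 against vehicle in GMP, edgeR found 8 of 100 genes changed 4-fold, so absent calls there do not show absent effects. All 35 splits gave at least the 0 genes called for Lys05, AC220, the combination against vehicle and the combination against Lys05 (highest other 0, 0, 1 and 1). For the combination against AC220, 11 of 35 gave as many as the 1 gene (highest other 6), so chance cannot be excluded there. The GMP interaction, with 0 genes, had 60 of 60 splits as large (highest other 2).

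For LSK against GMP with vehicle, 1 of 35 splits gave as many genes as the real 829 (highest other 1). For Lys05 against vehicle in LSK all 35 splits gave at least the 0 genes of the real one, and another split called 1142, which points to a structure among the 8 libraries that is not the treatment. For the LSK interaction, also 0 genes, all 60 splits gave as many, and 1 of them called 190.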

How the results depend on the processing

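The length and GC offset, the fits without 5 weakly correlated GMP libraries and the check of library numbers were chosen after the data were seen. No paired analysis was run because the labels give no number that links a library of one group to a library of another. The library numbers used here follow accession order and are not labels of animals, so they were not used for pairing. As a check, deviations over genes of LSK and GMP libraries with the same number correlated from -0.393 to 0.381, and 1 or 2 of the 4 LSK libraries of a treatment were closest to their own number, although the MHC class II scores did run alike (r from 0.393 to 0.988 by treatment). These values do not settle whether LSK and GMP libraries share animals. The tests between cell types treated the libraries as unpaired. The planned covariate for Y-linked expression was not run because all libraries had the same sex pattern.

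Leaving out 1 library at a time gave, in LSK, 0 to 198 genes for Lys05, 7897 to 9093 for AC220, 7222 to 8603 for the combination against vehicle, 0 to 138 against AC220, 7023 to 8408 against Lys05 and 0 to 4 for the interaction. In GMP it gave 0 to 0, 0 to 1, 0 to 5, 0 to 7, 0 to 22 and 0 to 1 in the same order. It gave 421 to 1403 for LSK against GMP with vehicle, 0 to 0, 2405 to 3654 and 1604 to 3022 for the difference between cell types in the Lys05, AC220 and combination effects, and 105 to 129 lists called, against 120 with all libraries. Correlations of effects ranged from -0.002 to 0.105 (Lys05 in LSK), 0.633 to 0.706 (AC220 in LSK), -0.068 to 0.012 (Lys05 in GMP), 0.040 to 0.201 (AC220 in GMP), 0.090 to 0.212 (Lys05 in LSK and GMP) and -0.079 to -0.002 (AC220 in LSK and GMP). The sign turned without LSK AC220 library 1 in the first and without GMP vehicle library 3 in the third.

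DESeq2 called 830 genes for Lys05, 339 for the combination against AC220 and 164 for the interaction in LSK. In GMP it called 10 for Lys05, 479 for AC220, 427, 926 and 508 for the combination against vehicle, AC220 and Lys05, and 307 for the interaction. It called 2071 for LSK against GMP and 248 and 3520 for the cell type differences with Lys05 and the combination. Voom with quality weights called 2113 for the combination against AC220 in LSK, 732, 214, 2, 0, 494 and 1 in GMP in the order above, 4329 for LSK against GMP and 5, 5564 and 3318 for the cell type differences with Lys05, AC220 and the combination. Fits of the groups of a comparison alone called 1 for Lys05 and 2 for the combination against AC220 in LSK, 0 for the latter in GMP and 1347 for the cell type difference with the combination. No filter on low counts gave 5 genes for the combination against AC220 in LSK, 6 against Lys05 in GMP and 513 for LSK against GMP, and RLE factors 4 for the combination against AC220 in LSK. The offset left 1 gene for the combination against AC220 in LSK. Without the weakly correlated libraries 1, 49 and 198 genes were called for the combination in GMP against vehicle, AC220 and Lys05, 5 for the interaction, 2646 for LSK against GMP and 5309 and 5412 for the cell type differences with AC220 and the combination. With an estimated correlation 15 of 120 lists kept their call and with fry 43. At a mean log2 CPM of at least 4 the correlations were 0.280 and 0.957 in LSK, -0.068 and 0.235 in GMP, 0.414 for Lys05 and 0.017 (the sign turned) for AC220 in LSK and GMP, and with the offset the last was -0.050. The cause was not tested except where fewer libraries or genes entered.

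Results that reversed were Mpo (-0.14, adjusted p = 0.674) and Cish (-0.33, adjusted p = 0.343) with AC220 in LSK and Gapdh (-0.019, adjusted p = 0.996) in the cell type difference with AC220, all with the offset. List medians that turned with the offset were ribosomal for the combination against Lys05 in LSK (0.12, from -1.13 to -0.97 over single libraries) and against AC220 in GMP (0.13; -0.47 to 0.056, the latter without GMP combination library 3), oxidative phosphorylation for the combination against AC220 in GMP (0.035; -0.36 to -0.11) and glycolysis for the cell type difference with the combination (-0.082; 0.60 to 1.262). In GMP these turned with voom or without the weakly correlated libraries: interferon with Lys05 (-0.034 with voom), glycolysis with AC220 (-0.042 and -0.10; -0.04 to 0.31, -0.044 without GMP vehicle library 1) and heat shock with AC220 (-0.10 without those libraries). Others turned without single libraries: sterol in the LSK interaction (0.028 without LSK combination library 1; -0.47 to 0.03), MHC class II for the combination against Lys05 in GMP (0.36 without GMP Lys05 library 1; -1.84 to 0.36) and mitochondrially encoded for the cell type difference with Lys05 (-0.43 without GMP vehicle library 1, the same without the weakly correlated libraries; -0.43 to 2.47). All these lost their call. Only results called with all libraries are listed here, so mitochondrially encoded genes with AC220 in LSK, which also turned with the offset, are not among them. The sign also turned, with the call kept, for the oxidative phosphorylation list with Lys05 in GMP (0.19 with voom, 0.12 without the weakly correlated libraries and 0.11 without GMP vehicle library 1, in a range from -0.37 to 0.11 over single libraries). Named genes were counted once per comparison, so that a gene can count more than once. Of 140 such results called, 112 kept direction and call with the offset and 139 in DESeq2. Of 261 such results 51 changed side of the threshold without some single library.

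Some settings moved the median of all genes by more than 0.1 in log2 units. The offset moved it by -0.18 for AC220, -0.21 for the combination against vehicle and -0.19 against Lys05 in LSK (-0.12 with RLE and -0.10 in DESeq2 for the last). In GMP with AC220 it moved by -0.12 with RLE and in DESeq2, -0.24 with voom, -0.13 with no filter or the groups alone and -0.12 without the weakly correlated libraries. For the combination in GMP the offset moved it by 0.12, 0.12 and 0.17 against vehicle, AC220 and Lys05, voom by -0.37, -0.11 and -0.39, and no filter by -0.16 against Lys05. For the GMP interaction it moved by 0.17 with the offset and -0.21 with voom, and for LSK against GMP by -0.11 with voom and -0.15 without the weakly correlated libraries. For the cell type differences it moved by 0.13 (offset) and 0.15 (weakly correlated libraries left out) with Lys05, -0.24 (offset) and 0.33 (voom) with AC220, and -0.31 (offset), -0.18 (RLE), -0.19 (DESeq2), 0.62 (voom) and 0.16 (weakly correlated libraries left out) with the combination. Depth ran from 35.7 M counts, and whether it limited calls was not tested.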

Other observations

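The comparisons of list scores and the reading by library below were chosen after the results were seen.

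Antigen presentation genes of dendritic cells had lower scores with the combination in both populations. The mean log2 CPM of the dendritic cell and MHC class II list was 7.49 with vehicle, 6.52 with Lys05, 6.97 with AC220 and 5.20 with the combination in LSK, and 5.28, 4.05, 4.98 and 2.41 in GMP. Against vehicle the combination differed by -2.29 in LSK and -2.87 in GMP, with no overlap between the 4 and 4 libraries in either (two-sided exact permutation p = 0.0286 each, the smallest possible for 4 against 4, adjusted p = 0.143 over 50 comparisons, so neither passed). The labels do not say whether LSK and GMP libraries come from the same animals, so the values in the populations are not taken as independent.

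Genes of tissue macrophages had higher scores with the combination in LSK, with scores of -1.53, -0.60, 0.12 and 1.47 with vehicle, Lys05, AC220 and the combination, and -0.62, 0.86, -0.28 and 2.36 in GMP. In LSK the combination was above vehicle by 3.0, above AC220 by 1.34 and above Lys05 by 2.07, and AC220 above vehicle by 1.65, each without overlap (exact p = 0.0286, adjusted p = 0.143). The 4 GMP combination libraries ran from -0.47 to 4.62. Other scores without overlap between libraries were the primary granule list in LSK with AC220 against vehicle (-0.96) and the combination against Lys05 (-0.63). The MYC and ribosome biogenesis list in LSK with the combination against vehicle (0.32) and the stem cell list in GMP with the combination against Lys05 (-0.81) had the same p and no overlap. The scores carry no length and GC offset. The median transcript length was 3928 bp for the tissue macrophage members tested in GMP and 1097.5 bp for the primary granule list. Score differences between LSK libraries with and without AC220 may therefore follow their short-transcript share. The macrophage scores in LSK, from -2.87 to 1.64 by library, also lie near the floor.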
